A study of Arabidopsis thaliana with 18 samples.

How the data were processed

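The data are 18 polyadenylated RNA libraries, made per the labels with a TruSeq kit of version 2, from leaves sprayed with estradiol or mock and sampled after 6, 12 and 24 h, 3 per group. Groups and replicate numbers were taken from the sample titles. The deposited values are raw read counts per gene, whole numbers not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.2, TopHat2 2.0.10 and HTSeq (no version given) with the TAIR10 genome. The annotation release, the strand setting and the counting mode are not given in the sources used here, so overlapping and antisense genes cannot be told apart and genes with near-identical copies are uncertain, as for EDS1 and AT3G48080, the CRK cluster, the LHCB and RBCS genes and PDF1.2. The table held 32678 genes, of which 8174 were at 0 in all libraries, and 5 classes of reads assigned to no gene. These classes held 5.76 to 6.71% of the reads in the table (no feature 0.53 to 0.83%, ambiguous 1.85 to 2.17%, not uniquely aligned 3.21 to 4.0%) and were left out of library sizes and tests. Gene names came from a table of assembly TAIR10.1, in which 31912 of the locus identifiers were found and 10297 had a symbol. As that assembly release is not the one named by the submitters, no coordinates are given. Genes without a symbol are named by locus identifier.

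The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with 1 coefficient for each of the 6 groups over all 18 libraries, TMM scaling, and filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19227 genes. The biological coefficient of variation was 8.3% with 12 residual degrees of freedom. P-values were adjusted over all tested genes by the Benjamini-Hochberg method and called below 0.05. Contrasts were estradiol against mock at each time, the differences between these effects, and mock against mock between times. CPM are TMM-scaled, with mean and SD over 3 libraries. The SE of a log2 fold change is its size divided by the square root of the F statistic, and fold changes use edgeR's default shrinkage of low counts, except that a gene with 1 to 3 counts in a group is given as a ratio of counts with an exact 95% interval. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 2.96 to 33.9), so no library was taken as a copy of another. Correlations between replicates of a group ranged from 0.987 to 0.994. The times separated on the leading principal components (58.9 and 27.9% of variance). The 10 most abundant genes took 10.5 to 11.0% of counts at 6 h, 5.57 to 6.0% at 12 h and 9.51 to 10.9% at 24 h.

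There were 26 lists of genes with 410 entries, fixed before the data were examined, as were the groups, designs, alternatives and the rule for named genes. They cover SA biosynthesis, pipecolic acid and NHP, EDS1 family and helper NLR, SA response, JA biosynthesis, the JAZ and MYC branch, the ERF branch, ABA and water deficit, cell-surface receptors and early signalling, NLR receptors, RPW8 homologs, cysteine-rich and wall-associated receptor kinases, camalexin and indole glucosinolates, aliphatic glucosinolates, ER chaperones, heat shock, xenobiotic detoxification, senescence, photosynthesis, clock, auxin, cell division, epidermal, vascular and flower markers and reference genes. Of the entries 405 were used, 391 with a matching name and 14 under the locus identifier; 5 whose locus has other names only were left out (CHS3, CSA1, HSP70-4, HSP23.6 and SAND), and PAD4 and EDS1 were in no list. Lists were tested with camera (limma 3.58.1; preset correlation 0.01, and again with an estimated correlation), which compares a list with other genes, and with fry, which tests whether its genes move on balance 1 way. Counts of members are given over all genes tested and adjusted over the list alone.

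The genes named for each comparison were PAD4 and EDS1, the 8 largest rises and 8 largest falls among called genes with a symbol, mean log2 CPM of at least 1 and no overlap between the groups' libraries, 15 SA and JA genes named whether called or not, up to 4 members of each called list, 5 genes for each difference between times, and up to 4 clock genes for each mock comparison. Other genes, such as the genes without a symbol called at 6 h and the members of uncalled lists, were chosen after their values were seen. Alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, only the libraries of the contrast, each library left out in turn, an adjusted p below 0.01 and a 2-fold minimum. Other splits of the libraries were refitted as a check on chance.

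The code was tested on simulated counts with 200 changed genes. In the simulated comparison of 6 h (19109 genes) 64.2%, 86.9% and 90.3% of changes of 1.5-fold, 2-fold and 4-fold were recovered and 8.3% of the calls were false. For 12 h (19125 genes) these were 76%, 77%, 98.4% and 5.8%, and for 24 h (19122 genes) 67.6%, 85.1%, 98.3% and 4.3%. These shares hold for 200 changed genes and for spreads estimated over all 18 libraries. The real comparison of 6 h gave 7 calls. With so few changed genes the adjusted threshold is stricter, so the recovery at 6 h may be lower than simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.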

Results

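Polyadenylated RNA was sequenced from leaves of the Arabidopsis thaliana line ED-P4E1, which carries PAD4 under an estradiol-inducible promoter and EDS1 under the constitutive 35S promoter in the Col-0 double mutant eds1-2 pad4-1. EDS1 and PAD4 are lipase-like proteins that act together in basal immunity and in immunity triggered by intracellular TIR receptors. Plants of 4 weeks, grown at 22 °C with a 10 h photoperiod, were sprayed with 10 µM estradiol or with a mock solution of 0.2% DMSO, each with 0.01% of the surfactant silwet, and leaves were taken after 6, 12 and 24 h. Each of the 6 groups held 3 libraries, 18 in all. The question of the series is which transcripts change first when EDS1 and PAD4 act together. No estradiol-treated line lacking the transgene was analysed here. Gene counts per library ranged from 19.1 to 48.1 M (M, 1e6 reads; median 28.9 M). A floor of 3 counts in 1 library corresponded to 0.0624 to 0.157 counts per 1e6 (CPM) before the TMM scaling used for all other CPM. Of 32678 genes 19227 were tested. Nothing in the labels says that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical.

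PAD4 (AT3G52430) was induced at every time. It reached 215 ± 73.9 CPM in estradiol-treated against 31.5 ± 2.50 in mock-treated leaves at 6 h (mean ± SD, n = 3), 308 ± 40.9 against 16.1 ± 0.219 at 12 h, and 252 ± 108 against 18 ± 2.52 at 24 h. The fold changes were 6.84, 19.1 and 14.1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p 0.000119, 1.88e-07 and 3.05e-08). EDS1 (AT3G48090) was abundant in both treatments, with 3077 ± 563 against 3329 ± 417 CPM at 6 h, 2090 ± 647 against 2343 ± 649 at 12 h and 4321 ± 652 against 4342 ± 373 at 24 h. It did not pass the test at any time (adjusted p 0.942, 0.686 and 0.990). Counting per locus does not separate transgene reads from reads of the mutated chromosomal PAD4 and EDS1 genes.

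**Figure D1:**
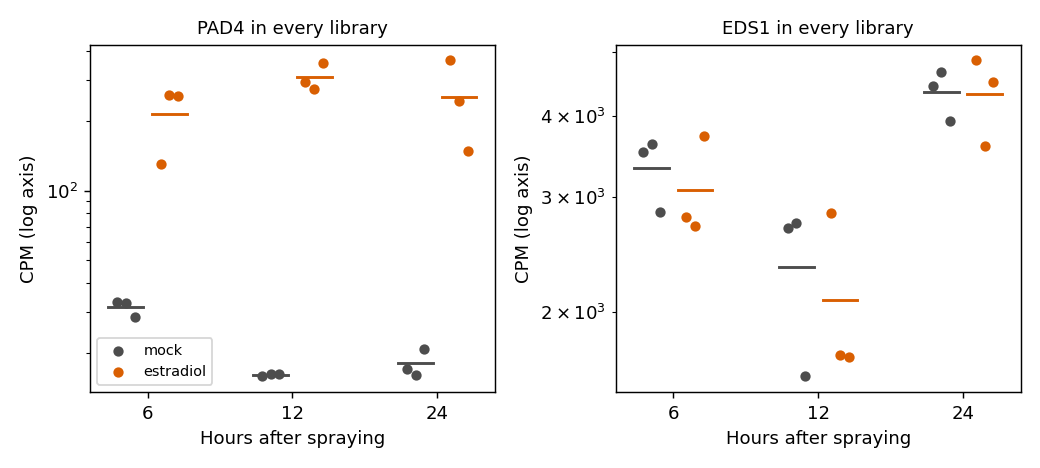
CPM (log axis) of PAD4 and EDS1 in each library against hours after spraying; points are libraries, bars are the means of 3 libraries, grey is mock and orange is estradiol. PAD4 lay between 130 and 364 CPM in the estradiol libraries and between 15.8 and 33.2 CPM in the mock libraries, while the EDS1 points of the treatments overlapped at each time.

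The comparison of estradiol with mock at 6 h asks which transcripts respond earliest. Besides PAD4, 4 genes rose and 2 fell. NAC036 (AT2G17040), a NAC-domain transcription factor, rose 2.01-fold, to 5.81 ± 0.222 from 2.85 ± 0.624 CPM (n = 3 per group, as throughout). RL4 (AT2G18328), a small MYB-like RADIALIS homolog, was 1.44-fold lower, at 36.4 ± 1.88 against 52.3 ± 1.06 CPM, and MES18 (AT5G58310), of the methylesterase family, was 1.68-fold lower, at 21.1 ± 1.65 against 35.5 ± 1.51 CPM. The other 3 genes that rose have no symbol in the reference names and were picked out after their values were seen: AT2G20142 rose 8.34-fold to 1.68 ± 0.804 CPM, AT5G39670 rose 8.85-fold to 2.00 ± 0.820 CPM and AT5G52760 rose 3.73-fold to 1.47 ± 0.168 CPM. The adjusted p values were 0.0285 for NAC036, 0.000252 for RL4, 0.00846 for MES18, 0.0285 for AT2G20142, 0.0331 for AT5G39670 and 0.00236 for AT5G52760. These 5 genes that rose, PAD4 included, and the 2 that fell compare with 1456 genes (7.6%) at an unadjusted p under 0.05, and 13.9% of the genes tested had groups that did not overlap, where chance gives 10%. DESeq2 called 24 genes higher and 16 lower, and limma-voom 1 and 2. The NAC036 call was lost with limma-voom, with only the 6 h libraries in the fit, and without any 1 of these 6 libraries (adjusted p up to 0.234). Those of AT2G20142 and AT5G39670 were lost with limma-voom, with only the 6 h libraries, and without any mock replicate or estradiol replicate 3 (up to 0.423 for each), and that of AT5G39670 also without estradiol replicate 2 (0.0876). AT5G52760 was lost with limma-voom and with only the 6 h libraries (0.180 and 0.161), so that PAD4 and RL4 alone kept the call in all 14 fits, thresholds aside. RL4 and MES18 did not reach 2-fold. The higher genes numbered 1 in each of these 2 fits, 2 without any mock replicate or estradiol replicate 3, and 3 and 4 without estradiol replicates 2 and 1. The MES18 call was lost without mock replicate 1 or 2 or estradiol replicate 1 (up to 0.0718).

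None of the salicylic acid (SA) genes examined passed the test at 6 h. ICS1 (AT1G74710), the isochorismate synthase of SA synthesis, was at 16.9 ± 1.31 against 16.3 ± 1.17 CPM. Its regulators SARD1 and CBP60g were 1.26-fold and 1.32-fold of mock, PBS3, the enzyme that conjugates isochorismate to glutamate, 1.23-fold, and WRKY70 1.32-fold lower (adjusted p 0.804, 0.699, 0.715 and 0.760). PR5 (AT1G75040), a thaumatin-like SA marker, was at 123 ± 20.1 against 82.1 ± 12.2 CPM (adjusted p 0.215, but 0.0164 with DESeq2), and PR2, a glucanase, at 9.30 ± 5.11 against 5.06 ± 1.88 CPM (adjusted p 0.570). EDS5, the transporter of the SA precursor, was 1.69-fold and ICS2 1.28-fold of mock (adjusted p 0.570 and 0.392). For these, PR5 and PBS3 the libraries of the treatments did not overlap. EDS5 was high in estradiol replicate 3, at 11.04 CPM against 4.696 and 4.625 CPM in estradiol replicates 1 and 2. That library was also the highest for SARD1 (4.371 CPM), CBP60g (4.899 CPM) and PR2 (15.07 CPM). Without it the log2 fold change of SARD1 at 6 h was −0.06. For PR5 and ICS2 it was instead the lowest estradiol library, at 104.1 and 13.79 CPM. PR1 had 0 counts in all 6 libraries, and the floor of 3 counts was 0.133 CPM before TMM scaling in the shallowest of them. NIMIN1 was at 0.242 ± 0.161 against 0.209 ± 0.0362 CPM, and ALD1, an aminotransferase of pipecolic acid synthesis, at 0.291 ± 0.401 against 0.314 ± 0.129 CPM. FMO1, which hydroxylates pipecolic acid, had 5 counts against 1, a ratio of 5.90 (exact 95% interval 0.66 to 279). On the log2 scale ALD1 at 6 h moved from −0.06 to −2.28 and NIMIN1 at 6 h from 0.23 to −0.38 without estradiol replicate 3. FMO1 at 6 h moved from 2.19 to 1.54 without estradiol replicate 3 and to 4.08 without mock replicate 1.

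Of the 26 gene lists, 8 were called at 6 h by camera with a preset correlation, although no member passed the test over all genes. These were SA biosynthesis (adjusted p 0.0113; 1 of 10 members higher when adjusted over the list alone), jasmonate (JA) biosynthesis (0.0277; none of 14), the JAZ and MYC branch of the JA response (0.0141; none of 23), the abscisic acid (ABA) response (4.39e-05; none of 18). They further included cysteine-rich and wall-associated receptor kinases (0.0107; 2 of 22), tryptophan and camalexin synthesis (0.000286; none of 19) and endoplasmic reticulum (ER) chaperones (2.05e-05; none of 18). These 7 moved upward, and intracellular NLR receptors (0.00970; none of 17) downward. With DESeq2 the receptor kinases CRK6 and CRK14 passed over all genes (adjusted p 0.0401 and 0.0498). All 8 were lost with an estimated correlation (adjusted p = 0.825 for SA biosynthesis, the ABA response, receptor kinases, camalexin and ER chaperones with an estimated correlation, 0.895 for both JA lists and 0.851 for the NLR receptors), and with fry. With the preset correlation, other splits of the same libraries called up to 12 lists at 6 h. Such splits called up to 14 lists at 12 h and up to 16 at 24 h, as many as the real split or more. The JA genes, such as TAT3 at 11.1 ± 16.2 against 2.88 ± 1.25 CPM, LOX2 at 6852 ± 3316 against 4953 ± 337 CPM, VSP2 at 766 ± 666 against 532 ± 31.4 CPM and MYC2 at 190 ± 112 against 133 ± 1.07 CPM, were high in 1 library. The median over 37 JA genes relative to the mock mean was 1.07 (log2) in estradiol replicate 3 but 0.01 and −0.18 in estradiol replicates 1 and 2. Without estradiol replicate 3 only the ABA and NLR lists were called, and JA biosynthesis, the JAZ and MYC branch and camalexin turned downward; without mock replicate 2, 4 lists were called. Without estradiol replicate 1, 11 lists were called, adding heat shock, detoxification and the clock (adjusted p 0.0176, 0.00930 and 0.0370). Leaving out estradiol replicate 2 added cell-surface receptors and auxin (0.0312 and 0.000284), and leaving out mock replicate 3 added photosynthesis (0.0279). The median and mean of the pipecolic acid list (−0.03 and 0.25) differed in sign, as did those of the vascular list (−0.01 and 0.03), and the auxin list had a median of 0.07 and a mean of 0.12 with the test downward. Among the lists without a call, 2 SA response genes were higher and 2 lower when adjusted over the list alone, and 1 RPW8 homolog and 1 epidermal marker higher.

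**Figure D2:**
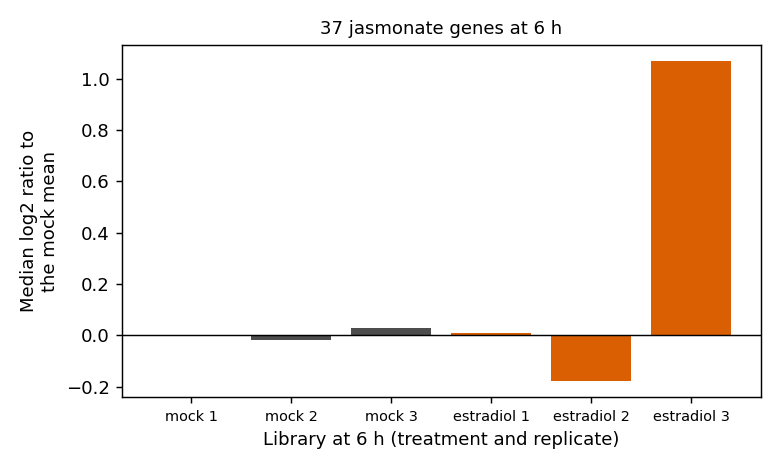
Median log2 ratio to the mean of the mock libraries over 37 jasmonate genes, 1 bar for each of the 6 libraries of 6 h (grey mock, orange estradiol). Estradiol replicate 3 stands at 1.07, and the other 5 libraries lie between −0.18 and 0.03.

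At 12 h, 892 genes were higher and 975 lower in estradiol-treated leaves, most by small amounts (median size 0.37 on the log2 scale), and 222 of the higher but 19 of the lower genes differed by at least 2-fold. Among the largest rises was that of AIG1 (AT1G33960), a GTP-binding protein first found as induced by a bacterial effector, at 3.88 ± 1.06 against 0.168 ± 0.240 CPM (25.3-fold). UGT76B1 (AT3G11340) is a glucosyltransferase of SA and N-hydroxypipecolic acid (NHP) and was at 12.2 ± 6.99 against 1.099 ± 0.660 CPM (11.2-fold). PR1 (AT2G14610) was at 4.096 ± 2.62 against 0.422 ± 0.252 CPM (9.09-fold). BIP3, an ER chaperone, rose 7.67-fold, PNP-A, a natriuretic-peptide homolog, 7.03-fold, IOS1, a leucine-rich repeat receptor kinase, 4.36-fold, PBS3 4.095-fold and UGT73B4, a glucosyltransferase, 3.68-fold (adjusted p from 2.80e-05 to 0.0376 over these 8 genes). The largest falls were in GSTF12 (AT5G17220), a glutathione transferase needed for anthocyanin transport, 3.51-fold lower, AGP17 (AT2G23130), an arabinogalactan protein, 3.06-fold lower at 3.76 ± 0.596 against 11.5 ± 1.31 CPM. Next were EXO, a brassinosteroid-responsive cell wall protein, 2.70-fold, COPT2, a copper transporter, 2.06-fold, AMT1;2, an ammonium transporter, 1.99-fold, and NIA1, a nitrate reductase, 1.91-fold lower. ATTPPA, a trehalose phosphate phosphatase, was 1.88-fold and RVE2, a clock-related MYB factor, 1.87-fold lower at 30.7 ± 3.37 against 57.5 ± 8.22 CPM (adjusted p from 4.78e-05 to 0.0136 over these 8 genes). Some of these sizes rest on 1 library. On the log2 scale AIG1 at 12 h moved from 4.66 to 7 without mock replicate 1 and 3.97 without mock replicate 3, and to 5.88 with limma-voom. PR1 at 12 h moved from 3.18 to 2.53 without estradiol replicate 2 and 3.85 without mock replicate 3. Without estradiol replicate 1 PNP-A at 12 h moved from 2.81 to 2.21 and IOS1 at 12 h from 2.13 to 1.48, and without estradiol replicate 3 GSTF12 at 12 h from −1.81 to −2.42.

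SA response genes had the smallest list p at 12 h. Of 25 SA response genes 20 rose and none fell (23 rose when adjusted over the list alone; camera adjusted p 4.26e-31, and 0.0107 with an estimated correlation). WRKY51 rose 18.7-fold, NIMIN1 (AT1G02450), which binds NPR1, 3.16-fold to 3.14 ± 0.429 from 0.964 ± 0.597 CPM, WRKY46 3.10-fold, NIMIN2 2.49-fold and DMR6, an SA hydroxylase, 2.47-fold. PR2 rose 3.21-fold to 14.6 ± 3.66 from 4.57 ± 0.491 CPM, WRKY70 2.37-fold to 136 ± 7.81 from 57.2 ± 23.0 CPM, and PR5 1.44-fold. Of 10 SA biosynthesis genes 3 rose (5 when adjusted over the list alone; adjusted p 4.46e-05): PBS3, ICS1 2.35-fold to 11.7 ± 3.39 from 4.998 ± 0.342 CPM, and SARD1 2.01-fold to 28.4 ± 1.12 from 14.1 ± 1.76 CPM. CBP60g was at 12.3 ± 3.54 against 8.52 ± 0.554 CPM (adjusted p 0.0549, but 0.0443 with DESeq2 and 0.0299 with limma-voom). That list call was lost at adjusted p = 0.0794 with an estimated correlation. Of 8 genes of the pipecolic acid and NHP pathway 4 rose (7 over the list alone; 1.59e-05, lost at adjusted p = 0.0767 with an estimated correlation). Among them ALD1 rose 13.6-fold, and FMO1 had 79 counts against 2, a ratio of 36.5 (exact 95% interval 9.77 to 306). The log2 fold change of FMO1 at 12 h, 4.87, moved to 7.33 without mock replicate 1 and 4.25 without mock replicate 3. Intervals and floors cover counting error only.

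Cysteine-rich and wall-associated receptor kinases rose as a second group at 12 h, 16 of 22 and none falling (17 up and 1 down when adjusted over the list alone; camera adjusted p 7.97e-19, and 0.0304 with an estimated correlation). CRK7 rose 6.75-fold, CRK6 2.61-fold to 34.4 ± 6.86 from 13.2 ± 1.94 CPM and CRK45 2.34-fold. These kinases lie in clusters of similar genes, so reads may be shared among them. Only this list and the SA response held with an estimated correlation at 12 h, and the other 10 called lists were lost. With fry 10 of the 12 called lists held, and the camalexin and heat shock lists were lost. Of 26 cell-surface receptor and early signalling genes 13 rose (18 over the list alone; adjusted p 6.27e-10, but adjusted p = 0.0767 with an estimated correlation). Among them were MPK11, a MAP kinase, at 1.96-fold, LYK5, a chitin receptor kinase, at 1.75-fold and SOBIR1, a co-receptor of receptor-like proteins, at 1.70-fold. Of 7 EDS1-family and helper NLR genes 6 rose (6 up and 1 down over the list alone; 1.76e-06, but adjusted p = 0.0794 with an estimated correlation), including ADR1-L2 at 1.57-fold, ADR1-L1 at 1.41-fold and SAG101, an EDS1 partner, at 1.38-fold. Of 18 ER chaperone and secretion genes 12 rose (14 over the list alone; 3.49e-13, but adjusted p = 0.0906 with an estimated correlation), with ERDJ3A at 2.13-fold and PDIL1-2, a disulfide isomerase, at 1.57-fold. Of the 2 RPW8 homologs, HR3 rose 1.56-fold (both over the list alone; 0.0270, but adjusted p = 0.200 with an estimated correlation), a list call lost without any 1 of the 6 libraries.

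Detoxification and secondary metabolism genes also moved at 12 h. Of 16 xenobiotic detoxification genes 10 rose (14 over the list alone; adjusted p 3.08e-07, but adjusted p = 0.240 with an estimated correlation), such as the glucosyltransferases UGT73B3 at 3.05-fold and UGT74E2 at 2.92-fold, and CYP81D8, a cytochrome P450, at 2.89-fold. In tryptophan, camalexin and indole glucosinolate synthesis 6 of 19 genes rose and 1 fell (7 up and 1 down over the list alone; 0.000459, but adjusted p = 0.454 with an estimated correlation). The camalexin enzymes PAD3 and CYP71A13 rose 3.45-fold and 3.27-fold, GSTF6 2.42-fold and PEN2, a myrosinase, 1.29-fold. MYB34, a regulator of indole glucosinolates, fell by 0.32 on the log2 scale. Of 15 aliphatic glucosinolate genes 5 fell and none rose (7 over the list alone; 2.45e-05, but adjusted p = 0.192 with an estimated correlation). They include the regulators MYB29 and MYB28, 1.37-fold and 1.31-fold lower, and the sulfotransferase SOT18, 1.25-fold lower. Of 9 heat shock genes HSP90.1 and HSFA2 rose, 2.25-fold and 2.31-fold (2 over the list alone; 0.0218, but adjusted p = 0.451 with an estimated correlation). HSP17.6II had 17 counts against 3, a ratio of 5.23 (1.51 to 27.9), which did not pass (adjusted p 0.185). On the log2 scale HSP17.6II at 12 h moved from 2.23 to 1.28 without estradiol replicate 2. It moved to 1.58 without mock replicate 3 and to 3.09 without mock replicate 2.

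The other 14 lists were not called at 12 h. No gene of JA biosynthesis passed, 1 of 23 genes of the JAZ and MYC branch fell (MYC4, 1 also over the list alone; camera adjusted p 0.0570), and VSP2 was at 25.3 ± 9.28 against 94.6 ± 56.5 CPM (adjusted p 0.0768, but 0.0147 with only the 12 h libraries; log2 fold change −1.91, and −1.32 without mock replicate 2). The JAZ and MYC list was called downward with DESeq2 size factors, and without mock replicate 2, mock replicate 3 or estradiol replicate 1 (adjusted p 0.0470, 0.00245 and 0.0272), but without mock replicate 1 its adjusted p was 0.650. These calls used the preset correlation, and with an estimated correlation over all libraries its adjusted p was 0.833. The NLR list was called upward without mock replicate 3 (0.0276) and senescence without estradiol replicate 3 (0.0367). MYC2, LOX2 and JAZ10 had adjusted p of 0.854, 0.830 and 0.269. In the ERF branch 1 of 12 genes rose (1 over the list alone), in the ABA list 1 of 18 (0 over the list alone), and in the NLR list 2 of 17 rose and 1 fell (3 and 1). In photosynthesis LHCB1.1 rose and RBCS2B and RCA fell of 25 (1 and 2). In the clock PRR7 rose 1.35-fold and COL2 fell by 0.30 on the log2 scale of 20 (2 and 1). LTP1 rose among 13 epidermal markers and GAPC1 among 10 reference genes (1 each over the list alone). None passed among 11 senescence (3 up and 1 down over the list alone), 16 auxin, 12 cell division and 11 vascular genes and the 1 measured flower marker (0 over each of these 4 lists). The median and mean of the reference genes differed in sign (−0.01 and 0.06, test upward), and the photosynthesis list had a median and mean of 0.02 with the test downward.

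The counts at 12 h leaned on single libraries: without estradiol replicate 1 they were 270 and 281, and without mock replicates 1, 2 and 3 the higher genes numbered 582, 438 and 432 and, for the last 2 of these, the lower genes 544 and 510. Calls lost without a library or with another tool or fit were those of UGT73B4 (adjusted p up to 0.285), UGT74E2 (0.227), HSFA2 (0.211), HSP90.1 (0.190), PAD3 (0.137), HR3 (0.136), COPT2 (0.118), GSTF6 (0.114), PEN2 (0.0969), NIA1 (0.0784), GSTF12 (0.0775), PR5 (0.0758), EXO (0.0738), MYB29 (0.0726), AMT1;2 (0.0700), CYP81D8 (0.0596), FMO1 (0.0587) and MYB28 (0.0513). All were lost without estradiol replicate 1 except EXO, lost without mock replicate 2. The calls of UGT73B4, PAD3 and UGT74E2 were also lost with DESeq2 and that of HSFA2 with limma-voom, and UGT74E2 at 12 h moved from 1.55 to 0.96 (log2) without estradiol replicate 1. The heat shock list was lost without mock replicate 1 or estradiol replicate 1 (0.0649 and 0.0711).

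**Figure D3:**
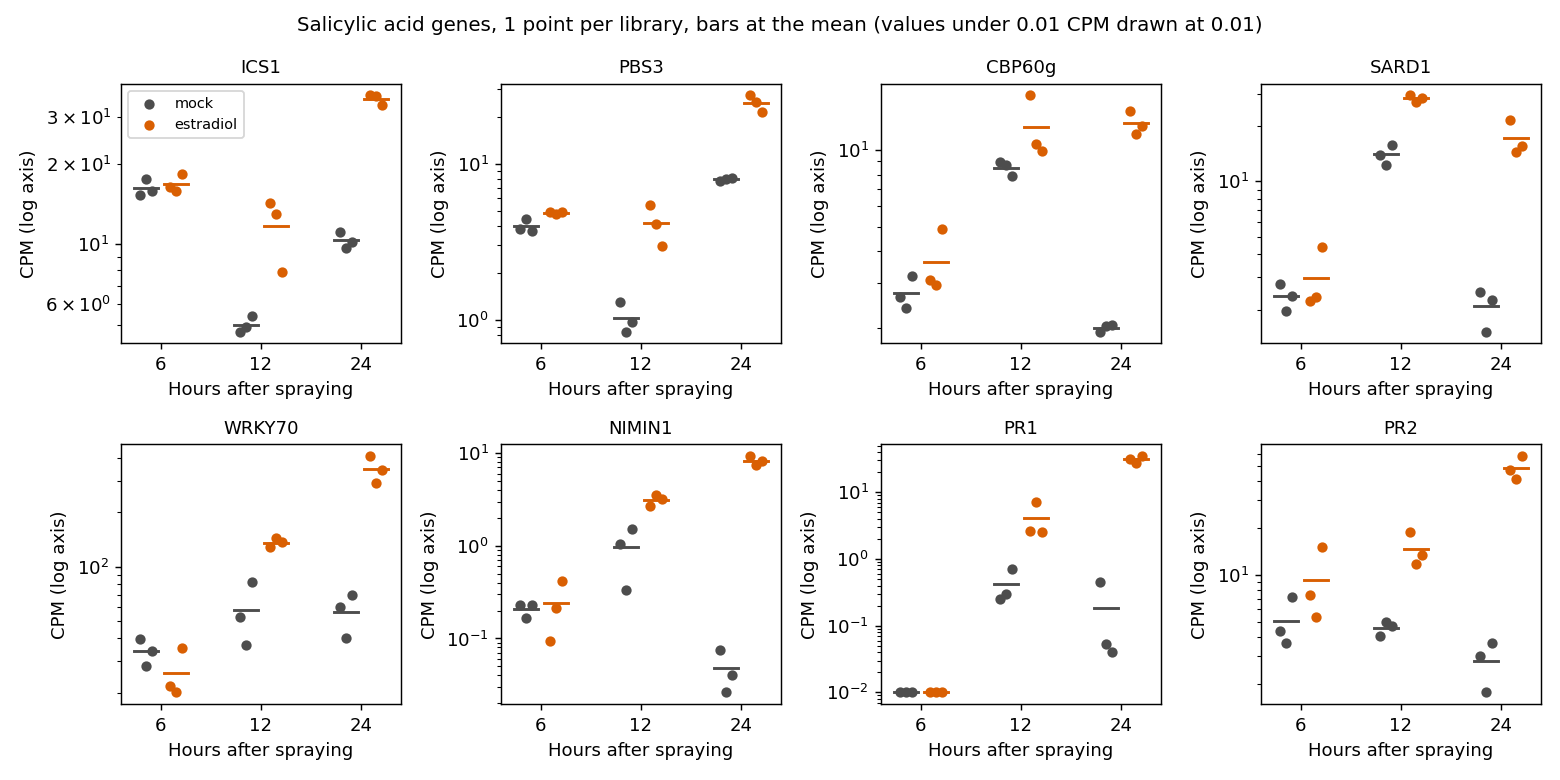
CPM (log axis) of 8 salicylic acid genes in each library against hours after spraying; points are libraries, bars are means of 3, grey is mock and orange is estradiol, and values under 0.01 CPM, as for PR1 at 6 h, are drawn at 0.01. At 24 h all 8 genes are higher in each estradiol library than in any mock library, as for ICS1 at 35.1 ± 1.62 against 10.4 ± 0.742 CPM.

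At 24 h, 1620 genes were higher and 1257 lower (518 and 26 by at least 2-fold). AIG1 rose 205-fold, to 21.7 ± 1.13 from 0.118 ± 0.121 CPM, PR1 181-fold to 31.3 ± 3.56 from 0.183 ± 0.237 CPM, NIMIN1 171-fold to 8.32 ± 0.924 from 0.0474 ± 0.0257 CPM and UGT76B1 102-fold (adjusted p 5.78e-09, 3.17e-07, 9.25e-09 and 1.01e-05). BIP3 rose 42.9-fold to 10.2 ± 3.36 CPM, NUDT6 (AT2G04450), a Nudix hydrolase, 36.4-fold to 35.3 ± 1.93 CPM, PNP-A 29.8-fold and TAT3 (AT2G24850), a JA-responsive tyrosine aminotransferase, 27.3-fold to 12.8 ± 4.05 from 0.448 ± 0.0660 CPM. The largest falls were in NUDT24, a Nudix hydrolase, 3.23-fold lower, GolS3, a galactinol synthase, 3.13-fold, EXPA16, an expansin, 2.52-fold, COR15A (AT2G42540), a chloroplast cold-protection protein, 2.27-fold at 73.9 ± 8.75 against 168 ± 41.0 CPM. BGLU47, a beta-glucosidase homolog, was 2.22-fold, the wax genes CER1 and WSD1 1.96-fold and 1.94-fold, and ELP, an extensin-like protein, 1.95-fold lower (adjusted p from 5.88e-06 to 0.0130). Mock levels near the floor leave the size of some rises open. On the log2 scale PR1 at 24 h moved from 7.50 to 9.24 without mock replicate 1, which held 12 of its 15 mock counts. AIG1 at 24 h moved from 7.68 to 6.91 without mock replicate 2, to 8.74 without mock replicate 3 and to 8.35 with limma-voom, and UGT76B1 at 24 h from 6.68 to 7.39 without mock replicate 2.

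Of 25 SA response genes 24 rose at 24 h (25 when adjusted over the list alone), with a median of 7.99-fold (camera adjusted p 3.09e-88, and 0.000105 with an estimated correlation). NIMIN2 rose 24.8-fold, AED1, a secreted aspartyl protease, 12.1-fold, DMR6 7.82-fold, PR2 18.1-fold to 48.8 ± 8.29 from 2.80 ± 0.967 CPM, WRKY70 6.21-fold to 348 ± 59.9 from 56.3 ± 14.98 CPM, and PR5 2.24-fold. WRKY51 had 292 counts against 2, a ratio of 201 (exact 95% interval 55.1 to 1666). In SA biosynthesis 4 of 10 genes rose and 1 fell (5 and 2 over the list alone). Those rising were SARD1 8.52-fold, CBP60g 6.33-fold to 12.7 ± 1.305 from 2.01 ± 0.0624 CPM, ICS1 3.40-fold and PBS3 3.08-fold. ICS2, a second isochorismate synthase, fell by 0.61 on the log2 scale. The list was called upward (adjusted p 4.995e-07). Of 8 genes of the pipecolic acid and NHP pathway 5 rose (5 over the list alone; 5.88e-08), with AT5G55450 at 19.3-fold, and AT5G52810 at 1.92-fold. ALD1 was at 114 counts against 1, a ratio of 157 (27.6 to 6246), and FMO1 at 63 counts against 3, a ratio of 28.9 (9.44 to 144). The log2 fold change of ALD1 at 24 h, 6.81, moved to 8.66 without mock replicate 2 and 6.07 with limma-voom, and that of FMO1 at 24 h, 4.64, to 3.15 without estradiol replicate 1 and 3.68 with limma-voom.

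Immune receptors and secretion genes rose at 24 h as well. Of 22 cysteine-rich and wall-associated receptor kinases 17 rose and CRK21 and CRK22 fell (19 and 2 over the list alone; camera adjusted p 4.10e-36), with CRK7 at 42.6-fold, CRK45 at 9.69-fold, CRK6 at 8.59-fold and WAK2 at 2.57-fold. Of 18 ER chaperone and secretion genes 17 rose (18 over the list alone; 4.28e-57), among them PDIL1-2 at 3.16-fold, CRT3, a calreticulin, at 2.87-fold to 104 ± 11.2 from 36.3 ± 3.29 CPM, and PDIL1-1 at 2.48-fold. Of 26 cell-surface receptor and early signalling genes 16 rose and RBOHF, an NADPH oxidase, fell (16 and 1 over the list alone; 9.25e-18). RLP23, the receptor of an nlp peptide, rose 13.7-fold, MPK11 10.2-fold, SOBIR1 4.58-fold to 131 ± 16.4 from 28.7 ± 3.55 CPM and LYK5 3.25-fold. Of 7 EDS1-family and helper NLR genes 6 rose (6 over the list alone; 2.27e-15): AT5G66910 2.70-fold, ADR1-L1 2.66-fold and ADR1-L2 2.08-fold. AT3G48080, a near-identical neighbour of EDS1 whose reads could be shared with it, rose 9.87-fold. EDS1 itself was at 4321 ± 652 against 4342 ± 373 CPM, which argues against reads shared from EDS1 as the source of this rise. Both RPW8 homologs rose (both over the list alone; 2.51e-08), HR4 5.70-fold and HR3 3.89-fold. With an estimated correlation these 5 lists, the SA response, SA biosynthesis and the NHP pathway were called (adjusted p from 0.000105 to 0.0183), and the other 8 called lists were not. With fry 16 lists were called at 24 h, with photosynthesis lost among these 8 and vascular markers added.

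Of those 8 lists, 4 were called upward at 24 h. In the ERF branch of JA and ethylene response 7 of 12 genes rose (9 over the list alone; adjusted p 8.24e-05, but adjusted p = 0.171 with an estimated correlation). These include ORA59, a JA and ethylene regulator, at 4.46-fold, ERF104 at 3.22-fold and HEL, the PR4 protein, at 3-fold. Of 17 NLR receptor genes 7 rose (9 over the list alone; 2.11e-05, but adjusted p = 0.291 with an estimated correlation), such as ZAR1 at 1.74-fold, RPM1 at 1.39-fold and RPS4 at 1.27-fold. Of 9 heat shock genes 6 rose (7 over the list alone; 5.95e-07, but adjusted p = 0.0528 with an estimated correlation), including HSP90.1 at 3.74-fold, ROF2 at 2.52-fold and HSP101 at 1.81-fold. Of 16 xenobiotic detoxification genes 6 rose (10 over the list alone; 4.17e-05, but adjusted p = 0.301 with an estimated correlation), with CYP81D8 at 5.77-fold, GSTU4 at 5.25-fold and UGT73B3 at 3.76-fold.

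The other 4 were called downward. Of 18 ABA and water deficit genes 7 fell and none rose (9 over the list alone; adjusted p 0.00265, but adjusted p = 0.289 with an estimated correlation), with COR15A, RD29A at 1.80-fold, COR15B at 1.77-fold and RD22 at 1.32-fold lower. Of 15 aliphatic glucosinolate genes 10 fell (12 over the list alone; 2.04e-07, but adjusted p = 0.0708 with an estimated correlation), with MYB28 1.46-fold and MYB29 1.39-fold lower. Of 13 epidermal markers 5 fell (6 over the list alone; 0.00716, but adjusted p = 0.148 with an estimated correlation): CER1, and by smaller amounts KAT1, LTP1, CER6 and ATML1. Of 25 photosynthesis genes 3 fell (4 over the list alone; 0.000983, but adjusted p = 0.504 with an estimated correlation), RBCS2B, LHCA1 and LHCA3, 1.25-fold, 1.21-fold and 1.15-fold lower. The camalexin and indole glucosinolate list was not called (0.135), except downward without mock replicate 1 (0.0424), and its members went both ways, 3 rising and 7 falling (4 and 8 over the list alone; median −0.10, mean 0.24). PAD3 rose 9.70-fold, GSTF6 4.81-fold and MYB51 2.11-fold. CYP79B3 fell by 0.95 on the log2 scale, and CYP79B2, MYB34, ASA1, TSB2, CYP83B1 and SUR1 also fell.

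The lists of JA biosynthesis and of the JAZ and MYC branch were not called at 24 h: no gene of JA biosynthesis passed, and TAT3 rose and JAZ3 fell among 23 genes of the JAZ and MYC branch (1 and 1 over the list alone). MYC2 was at 63.3 ± 8.90 against 107 ± 54.5 CPM, VSP2 at 10.4 ± 6.27 against 25.4 ± 21.1, LOX2 at 846 ± 211 against 1074 ± 533 and JAZ10 at 1.14 ± 0.435 against 1.26 ± 0.325 (adjusted p 0.115, 0.241, 0.494 and 0.848). The mock means of MYC2, VSP2 and LOX2 were raised by mock replicate 2, at 169, 48.0 and 1688 CPM. Without it the log2 fold changes of MYC2 and VSP2 at 24 h were −0.27 and −0.51, and that of LOX2 at 24 h turned to 0.14, while MYC2 at 24 h passed without mock replicate 1 (adjusted p 0.0407). Also without a call were senescence (SAG13 up and SAG29 down of 11), the clock (TOC1 up 1.39-fold and COL2 down of 20) and auxin (GH3.3, which conjugates auxin, up 8.53-fold of 16). The same holds for cell division (MCM2 and PCNA1 up of 12), vascular markers (SUC2 and SULTR2;1 down of 11), reference genes (UBC9 down of 10) and the flower marker AG, with the same counts when adjusted over the list alone. The mean and the median of the clock (0.04 and −0.05) and auxin lists (0.16 and −0.08) differed in sign. The lower genes numbered 551, 837 and 703 without mock replicate 2, estradiol replicate 1 and estradiol replicate 3, and 459 with only the 24 h libraries in the fit. Calls lost without a library or with another tool or fit were those of LHCA3 (adjusted p up to 0.254), LHCA1 (0.170), COR15B (0.161), RBCS2B (0.147), GolS3 (0.131), RD22 (0.0958), FMO1 (0.0876), ORA59 (0.0816), LTP1 (0.0806), KAT1 (0.0755), ATML1 (0.0688), RD29A (0.0682), WSD1 (0.0656), TAT3 (0.0552) and HEL (0.0517). Of these GolS3, ORA59, RD29A, RD22, COR15B, RBCS2B, LHCA1, LHCA3 and ATML1 were lost without mock replicate 2, and HEL, LTP1 and KAT1 with only the 24 h libraries. FMO1 was lost without estradiol replicate 1, TAT3 with limma-voom and WSD1 with DESeq2.

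**Figure D4:**
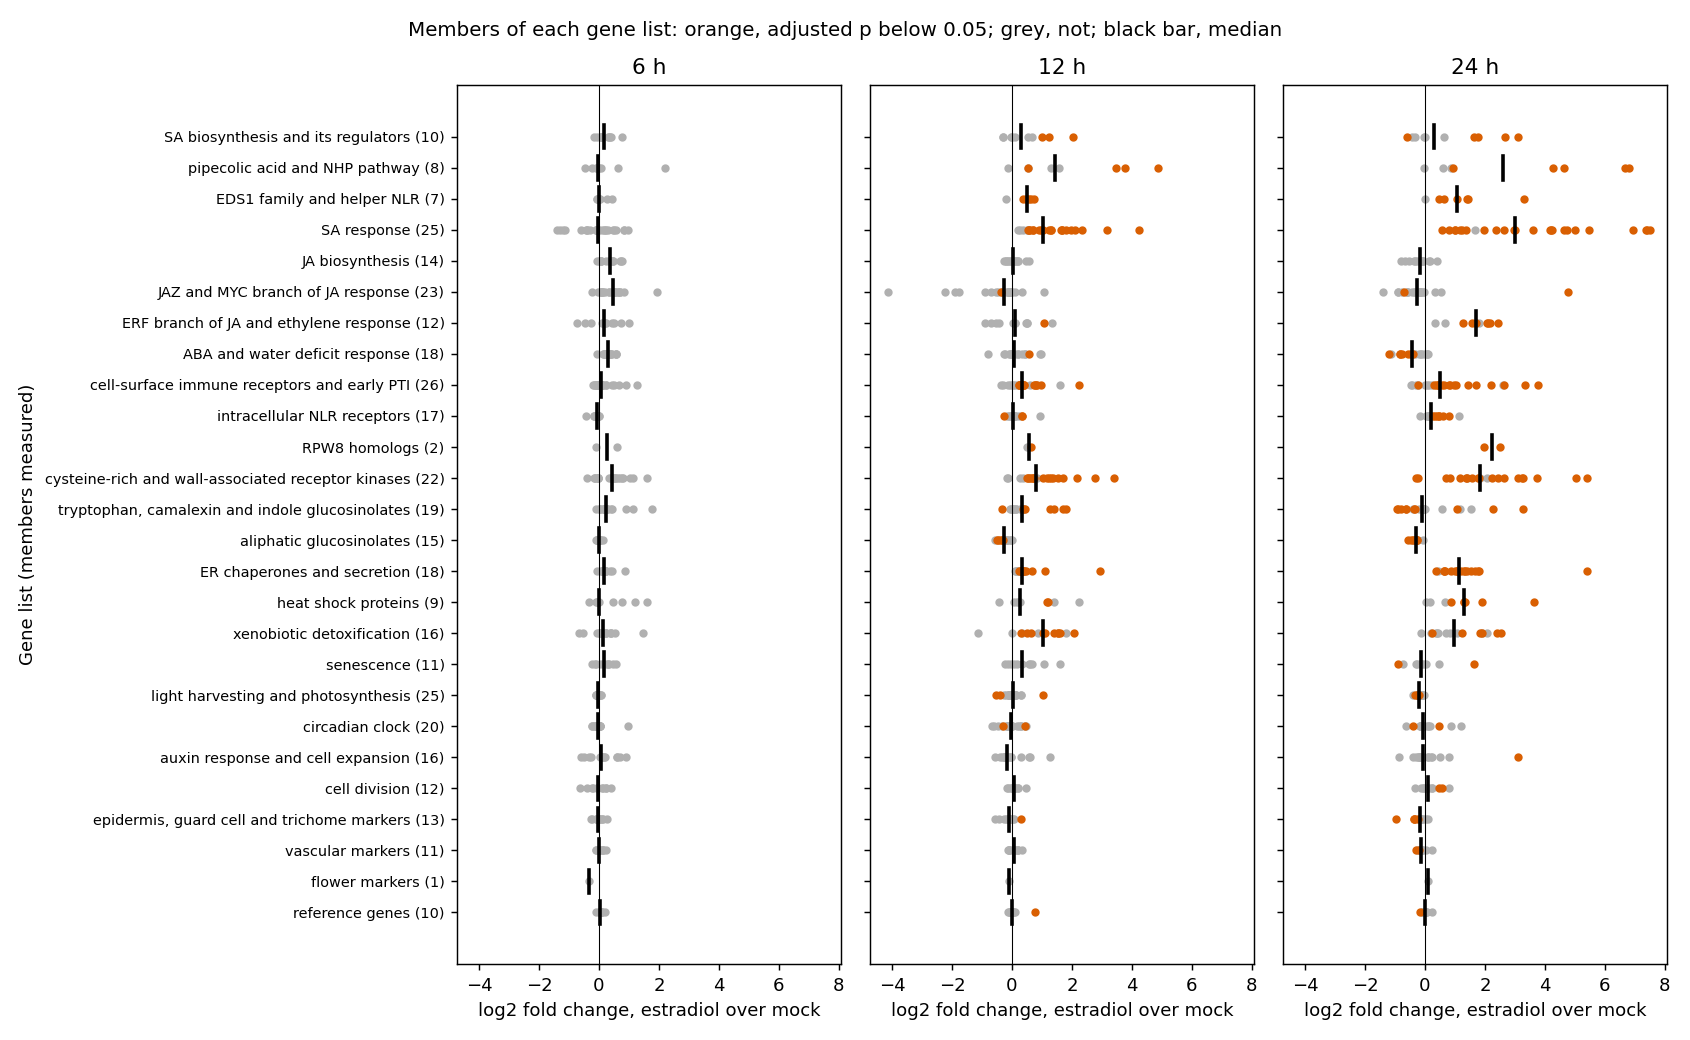
Log2 fold change (estradiol over mock) of each measured member of the 26 gene lists at 6, 12 and 24 h; each point is a gene, orange with adjusted p below 0.05 and grey otherwise, and black bars are medians, with the number of members in brackets. No member is orange at 6 h, 20 of 25 SA response genes are at 12 h and 24 at 24 h.

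The genes called at 6 h stayed called later with 1 exception. The 5 higher genes were called higher at 12 and 24 h, where NAC036 rose 2.41-fold and 9.45-fold, AT5G39670 8.71-fold and 79.4-fold, AT5G52760 4.00-fold and 45.2-fold and AT2G20142 4.47-fold and 27.3-fold. RL4 was lower at both times, by 1.21-fold and 1.16-fold, and MES18 at 24 h (1.27-fold) but not at 12 h (adjusted p 0.0962). Of the 892 higher genes of 12 h, 586 (65.7%) were also higher at 24 h, against 75.2 for independent lists, and of the 975 lower genes 346 (35.5%) were lower at both, against 63.7. Genes called in opposite directions numbered 6, higher then lower, and 1, lower then higher, against 58.3 and 82.2. These comparisons shared no libraries. Across genes, which are not independent replicates, the fold changes of 12 and 24 h had r = 0.596 (Spearman's rho 0.488), those of 6 and 12 h r = 0.209 (0.159) and those of 6 and 24 h r = 0.186 (0.068), with 3 pairs compared.

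The differences between the estradiol effects were tested as such. From 6 to 12 h the effect differed in 152 genes, 60 upward and 92 downward, from 12 to 24 h in 407 (356 and 51) and from 6 to 24 h in 1160 (775 and 385). The effect on RLP41 (AT3G25010), a receptor-like protein, on AED1 and on SOBIR1 was greater at 24 than at 6 h by 3.75 ± 0.21, 3.297 ± 0.19 and 2.08 ± 0.15 on the log2 scale (estimate ± SE). That on NUDT6 and BG3, a beta-1,3-glucanase, was greater at 24 than at 12 h by 4.09 ± 0.25 and 4.05 ± 0.29. AGP17 and GLK2 (AT5G44190), a transcription factor of chloroplast development, moved downward from 6 to 12 h by −1.58 ± 0.24 and −0.54 ± 0.07. The count from 6 to 12 h fell to 7 without mock 12 h replicate 2 and to 6 at an adjusted p below 0.01. That from 12 to 24 h was 262, 232 and 240 without mock 12 h replicate 3, mock 24 h replicate 2 and estradiol 24 h replicate 1, and that from 6 to 24 h was 744 without mock 24 h replicate 2.

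The mock libraries give the course without induction. Between 6 and 12 h 12361 genes differed (6472 higher and 5889 lower at 12 h), between 12 and 24 h 14429 (6911 and 7518) and between 6 and 24 h 12733 (6600 and 6133), so that time changed more genes than estradiol did at any time. Of 20 clock genes 4 rose and 16 fell from 6 to 12 h, 12 rose and 8 fell from 12 to 24 h, and 10 rose and 9 fell from 6 to 24 h. PRR7, PRR5, LNK2 and LNK1, which act in the day, were 65.1-fold, 73.0-fold, 51.8-fold and 240-fold lower at 12 than at 6 h, PRR7 at 4.86 ± 0.749 against 314 ± 11.5 CPM. The morning factors CCA1 and LHY rose 2612-fold and 2385-fold from 12 to 24 h, CCA1 from 0.202 ± 0.0560 to 524 ± 19.8 CPM, with LNK2 at 410-fold and COL2 at 30.1-fold. From 6 to 24 h LHY rose 252-fold, CCA1 19.9-fold and COL2 16.3-fold, and PRR5 was 498-fold lower. In the same hours estradiol changed PRR7 and COL2 at 12 h and TOC1 and COL2 at 24 h, each by less than 2-fold.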

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

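The tests of the JA library, of the time of day, of expression and length and of detoxification, given under the other observations, were chosen only after the result was seen; the tests on other splits of the libraries were chosen before.

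The effects of estradiol differed between times in tests of the difference itself, in 152 genes between 12 and 6 h, 407 between 24 and 12 h and 1160 between 24 and 6 h. Between 12 and 6 h, on the log2 scale and later minus earlier, the differences were −0.54 for GLK2, −0.55 for the aquaporin PIP1;4, −0.70 for the mechanosensitive channel homolog MSL5, 0.54 for EMB1290 and −1.58 for AGP17. Between 24 and 12 h they were 2.91 for AED1, 4.09 for NUDT6, 2.56 for RLP41, 4.05 for BG3 and 3.76 for PCR1. Between 24 and 6 h they were 3.75 for RLP41, 3.3 for AED1, 4.70 for PCR1, 4.16 for SIB1, a sigma factor binding protein, and 2.08 for SOBIR1.

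Regrouping the treatments within the times gave as many genes in 3 of 100 regroupings for 12 against 6 h, the real one included (highest other 359, real 152). It was 2 of 100 for 24 against 6 h (1419, real 1160) and 7 of 98 for 24 against 12 h (highest other 1771, real 407). The share lay under 0.05 for 12 and 24 h against 6 h and above it for 24 against 12 h. Shuffled treatments stand for no estradiol effect at either time, not for equal effects at both. These shares therefore cannot tell whether chance made the differences between effects. The regroupings with as many genes, 2, 6 and 1 besides the real ones, each kept the real split of the treatments, as it was or reversed, at 1 or more of the times. Those with no real split called at most 0, 1 and 1 genes. The high counts thus go with a structure of the samples, the real treatment split at 1 or more of the times.

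For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real and the highest other values were 5 and 0 for genes higher at 6 h, 2 and 0 for genes lower at 6 h, 892 and 1 for higher at 12 h and 975 and 0 for lower at 12 h. At 24 h they were 1620 and 121 for higher and 1257 and 197 for lower genes. They were 12361, 14429 and 12733 against 0 each for mock between times. For the number of gene lists called they were 8 and 12 at 6 h, 12 and 14 at 12 h and 16 and 16 at 24 h, with as many lists in 7, 4 and 2 of the splits, the real one included. The number of lists called with the preset correlation therefore does not by itself set the real split apart from other splits at any time.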

How the results depend on the processing

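Leaving out libraries for the list tests and all alternatives for the overlap were chosen only after the data were seen; the other tests were chosen before.

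Scaling and low-count filters left each count of genes within 1.5 times. With DESeq2 the genes at 6 h were 24 higher and 16 lower, and those differing between 12 and 6 h 406. With limma-voom 1 gene was higher at 6 h. With only the libraries of the contrast 1 gene was higher at 6 h, 459 were lower at 24 h and 247 differed between 12 and 6 h. At an adjusted p below 0.01, 2 were higher at 6 h, 322 higher and 355 lower at 12 h and 430 lower at 24 h. The differences then held 6, 191 and 541 genes (12 against 6 h, 24 against 12 h, 24 against 6 h), and the overlap of genes called at 12 and 24 h was 326 of 932. With a 2-fold minimum 0 were lower at 6 h, 222 higher and 19 lower at 12 h and 518 higher and 26 lower at 24 h. The differences then held 16, 184 and 370 genes, mock over time 3614, 6180 and 4288, the overlap 149, and of 142 calls among named genes 94 passed. A stricter threshold passes fewer genes by construction; for the tools and fits the cause was not tested. With an estimated correlation 0, 2 and 8 lists were called at 6, 12 and 24 h, and with fry 0, 10 and 16.

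Leaving out 1 library in turn, genes higher at 6 h ranged from 2 to 4 and lower from 1 to 5, at 12 h from 270 to 1070 and from 281 to 1083, and at 24 h from 1164 to 1620 and from 551 to 1370. The differences ranged from 7 to 287, 232 to 438 and 744 to 1354, mock over time from 11566 to 11687, 13703 to 14164 and 11946 to 12295, lists from 2 to 11, 10 to 13 and 16 to 17, and named genes from 123 to 143. Fewer libraries give less power, and beyond this the cause was not tested.

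With the replicate number as a block 5 genes were higher and 2 lower at 6 h, 789 and 844 at 12 h and 1525 and 1103 at 24 h, and 8, 12 and 16 lists were called. Whether the numbers pair the samples is not settled. Deviations of same-numbered libraries correlated at −0.01, 0.05 and 0.06 at 6 h, 0.17, −0.06 and 0.18 at 12 h and −0.16, 0.20 and 0.00 at 24 h. Estradiol replicates 2 and 3 at 6 h, 1 and 3 at 12 h and 2 at 24 h correlated best with the mock library of their own number. The others correlated best with another number. Among 2818 values of named genes under the alternatives, 2655 kept direction and side of the threshold, 119 fell short of it, 17 newly passed it, 0 turned with a call on either side and 27 changed sign without a call in either fit; 103 of 142 calls passed in every alternative fit, the stricter thresholds aside. Depth limits genes near the floor, such as PR1 at 6 h.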

Other observations

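The tests of gene families and of the 3 patterns in this part were chosen only after the result was seen.

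Families sharing a symbol were tested, 109 in all, some of them in part in the fixed lists. Of 44 receptor-like protein (RLP) genes 15 rose at 12 h and 19 rose and 1 fell at 24 h, with RLP39 at 43.4-fold, RLP41 at 13.7-fold, RLP34 at 11.6-fold and RLP37 at 4.34-fold at 24 h (camera adjusted p 5.54e-19, but adjusted p = 0.0784 with an estimated correlation). Of 44 WRKY transcription factors, 12 of which are in the fixed lists, 12 rose and 1 fell at 12 h and 17 rose and 1 fell at 24 h, among them WRKY38 at 123-fold, WRKY54 at 26.6-fold and WRKY53 at 5.16-fold (4.25e-10, but adjusted p = 0.131 with an estimated correlation). Of 48 NAC factors 9 rose at 12 h and 12 at 24 h, such as NAC004 at 22.7-fold, NAC016 at 9.44-fold and NAC061 at 11.5-fold (0.000261, but adjusted p = 0.378 with an estimated correlation). Of 19 calcium-dependent protein kinases 4 rose at 12 h and 9 at 24 h, with CPK31 at 2.90-fold and CPK29 at 2.45-fold (4.11e-05, but adjusted p = 0.144 with an estimated correlation). Also called upward at 24 h with the preset correlation were ABCC, CNGC, CRK, GSTF, HSP, NUDT and PDIL. Of these, 18 of 33 CRK, 5 of 16 HSP, 4 of 13 PDIL and 1 of 10 GSTF genes are in the fixed lists and so in part repeat their results. The NUDT family went both ways, with 4 of 17 genes rising, 3 falling and a median log2 fold change of −0.13. No family held with an estimated correlation at any time.

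Families were also called downward at 24 h. Of 12 plasma membrane aquaporins (PIP) 5 fell at 12 h and 9 at 24 h, as PIP2;8 fell by 0.58 and PIP2A by 0.44 on the log2 scale at 24 h (camera adjusted p 0.000160, but adjusted p = 0.378 with an estimated correlation). Of 13 fasciclin-like arabinogalactan proteins (FLA) 5 fell at 12 h and 6 at 24 h, FLA2 by 0.47 at 24 h (0.0209, but adjusted p = 0.751 with an estimated correlation). Of 19 CIPK genes 4 fell (0.0209, but adjusted p = 0.378 with an estimated correlation), and of 12 HCF genes 3 fell (0.0491, but adjusted p = 0.751 with an estimated correlation). The cell wall families EXPA, XTH and AGP were not called at 24 h: 1 of 14 EXPA genes fell (0.559), 1 of 20 XTH genes fell (0.369), and 2 of 24 AGP genes fell and 1 rose (0.494). The families were formed by the letters of the symbol alone, so members need not be related in sequence, as for HCF. Where members are near-identical copies, reads may be shared between them.

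At 6 h the JA genes were high in 1 estradiol library. Their median log2 fold change was 0.42 with all libraries and −0.08 (−0.081) without estradiol replicate 3, so the rise rests on that library. A mock-treated sample in its place is argued against by its PAD4 level, 256 CPM, far above the mock libraries (28.7 to 33.2 CPM). The values are consistent with wounding or another stress of that sample before harvest, but this was not tested and no label records one.

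The genes changed at 24 h followed the change of the mock leaves from 6 to 12 h. Of the genes higher at 24 h, 82.7% were higher in mock at 12 than at 6 h, against 51.9% of all genes, and of those lower 19.9% were; across the 2877 called genes r was 0.505 (rho 0.654) and the slope 0.407 ± 0.013 (SE), while over all genes tested r was 0.333. No library is shared. Over the 20 clock genes the slope was 0.036 (95% interval −0.013 to 0.084), below that of the called genes, and r was 0.344 (rho 0.198). At most this argues against a shift in sampling time between treatments along the course from 6 to 12 h. A shift near 24 h would follow the clock's course at that hour, which this slope does not test. In fry's test for change in either direction the clock list had an adjusted p of 1.06e-06 at 24 h. The auxin and cell division lists also passed that test (0.00053 and 0.00864), while the reference genes did not (0.0994). The clock value is thus not particular to a shift in sampling time, and such a shift stays open. A linear dependence on mean log2 CPM and log2 gene length does not account for the pattern among the called genes. The partial correlation given both was 0.452 over 2864 genes with a length. Other forms of dependence were not tested. Another explanation that stays open is that the genes induced by EDS1 and PAD4 overlap those that vary with the hour or with spraying. No unsprayed leaves were analysed here.

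Detoxification genes, 10 of 16 higher at 12 h and 6 at 24 h, may respond to estradiol itself without the transgene. This and an effect of EDS1 and PAD4 cannot be told apart, since no line without the inducible gene is among these samples. The median log2 fold change of the list at 6 h was 0.15 (0.147). By camera with the preset correlation the list was not called at that time with all libraries, but it was without estradiol replicate 1 (adjusted p 0.00930). Estradiol replicate 1 is the estradiol library of 6 h with the least PAD4 (130 CPM). With an estimated correlation over all libraries the adjusted p of the list at 6 h was 0.960.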
